A study of Mus musculus with 4 samples.

How the data were processed

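The data are RNA sequencing counts per gene from CD8+ T cells purified from mouse spleen and stimulated for 24 h with anti-CD3/CD28 beads. Per the labels' protocols, total RNA was extracted, mRNA was purified from it with a Dynabeads mRNA DIRECT Micro kit, and libraries were made with a stranded kit (KAPA Stranded RNA-Seq). The 4 libraries used have 2 replicates per genotype label, described as biological replicates. The description codes of the samples name the opposite genotype to the genotype field and title. Groups follow the genotype field and title, and the libraries are called labelled WT and labelled KO throughout. The columns of the table carry the description codes, and each was joined to its sample through that code.

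Per the file headers, the authors deposited a table of counts per gene, and its values are whole numbers with no normalization. Per the file headers, the authors also deposited FPKM, which is the count per kilobase of gene length and per 1000000 counts of the library. Dividing count by FPKM and by library total gave the same gene length in every library to within 0.0758%. The labels name the tool kallisto and the build GRCm38, with no version and no role given, and kallisto by itself estimates counts that are not whole numbers, so whether these counts came from it is not stated. Whether counting used strand, how reads of overlapping genes were divided and which filters were applied are not given in the sources used here. The table also holds 8 other columns of values, which were not used here.

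The table has 53465 genes. Of these, 53360 are in GENCODE M21 (GRCm38), and 96.37% of them lie at the same chromosome, start and end. That annotation gave overlaps and exon lengths. Of 10853 genes with at least 50 counts in 1 library, 16.5% had a gene length, as implied by count and FPKM, within 1% of the total exon length of that annotation, so the deposited lengths mostly differ from those used here. Where a gene name stood on more than 1 row, as 93 did, the one with the most counts was used for lists. Library totals were 12967251 and 17316284 counts for the labelled WT and 13394074 and 14199020 for the labelled KO libraries. The zero-count floor is 3 counts of a library's total, and it and all counting intervals cover counting error alone.

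Genes were filtered by filterByExpr of edgeR by label, which left 13528, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), labelled KO minus labelled WT, two-sided. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of F, and CPM are scaled by TMM. The biological coefficient of variation was 15.9% and the prior degrees of freedom 4.87. Spread between replicates was well beyond counting noise, with a chi-square over degrees of freedom of 19.2 for the labelled WT pair and 13.7 for the labelled KO pair. A single value in 2 against 2 libraries cannot pass an exact permutation test, so adjusted p values rest on the spread pooled across genes.

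Before the data were examined, 34 gene lists were fixed: the target, branched-chain amino acid breakdown, amino acid transporters, mTORC1 amino acid sensing, glycolysis and lactate export, the pentose phosphate pathway, pyruvate dehydrogenase and the TCA cycle, the nuclear-encoded respiratory chain, mitochondrially encoded transcripts, cytotoxic effector molecules and cytokines, effector transcription factors and receptors, naive and memory T cell genes, inhibitory receptors and exhaustion-associated genes, T cell receptor activation genes, cell cycle and DNA replication, ribosome biogenesis and MYC targets, the amino acid and integrated stress response, the unfolded protein response, sterol and fatty acid synthesis, fatty acid oxidation, hypoxia-inducible factor targets, type I interferon response, apoptosis and p53 targets, CD8 T cell identity, markers of B cells, of CD4 and regulatory T cells, of myeloid cells, of dendritic cells, of NK and gamma-delta T cells, of erythroid cells and platelets, and of stromal and endothelial cells, immediate-early and dissociation stress genes, core histone genes and sex-chromosome genes. Lists with at least 5 tested members were tested by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes tested, and fry tests whether a list's genes move one way on balance. Counts adjusted over the list alone use Benjamini-Hochberg within the list. Terms of the Gene Ontology that the table gives per gene, with 15 to 200 tested genes, were tested the same way after the data had been seen. Trends with transcript length and GC content were taken out by a loess fit of the signed test statistic, and the lists were then compared on its residuals by camera's test for precomputed statistics.

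The rule for named genes was fixed with the lists: Ppm1k, the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among those with a mean of at least 5 CPM, a symbol other than a predicted gene, and both libraries of 1 label above both of the other, up to 4 members with the smallest p of each list called by camera or with at least 2 called members, and 19 genes of glucose use, effector function, T cell state and branched-chain amino acid metabolism. Genes outside it are named as chosen after their values were seen. The values of 1 gene under this rule are not reported here.

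Alternatives planned before the data were examined were DESeq2 1.42.0, its size factors in edgeR, library size alone, no filter on low counts, at least 5 CPM in 2 libraries, protein-coding genes alone, a replicate block, each library left out in turn, a threshold of at least 2-fold and the other list tests. Where a library was left out, the lone library of its label was assumed to vary like the others. Added later were limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of at least 1 FPKM in 2 libraries, in place of planned fits on TPM, which the table does not hold, a crossed block and a fit without genes that share exons. The 2 other splits of the 4 libraries into pairs, replicates 1 against replicates 2 and a crossed split, were fitted the same way.

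The tests were run first on simulated counts for 13528 genes with the means and library sizes of these samples. Of 100 genes changed 2-fold, 54% were called, and of 100 changed 4-fold, 95%. Among 169 called genes, 17 were simulated unchanged. A list shifted by −0.4 on the log2 scale was called with an adjusted p of 7.88e-12, and 0 others were called. Genes were drawn independently of each other, so this cannot show how the list test behaves where a list's genes vary together. The correlation estimated from the data was, for example, 0.743 within the sterol and fatty acid synthesis list. Tables were read with Python 3.11.15 and pandas 2.3.3.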

Results

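RNA sequencing was read from CD8+ T cells purified from mouse spleen and kept for 24 h with beads that carry antibodies to CD3 and CD28. The antibodies mimic engagement of the T cell receptor and of the costimulatory receptor CD28. There were 4 libraries, 2 labelled wild type (WT) and 2 labelled PP2Cm knockout (KO). PP2Cm, the product of Ppm1k, is a mitochondrial phosphatase that activates the branched-chain ketoacid dehydrogenase, the enzyme complex that commits leucine, isoleucine and valine to breakdown. The libraries labelled WT held 12967251 and 17316284 counts, with 18671 and 19368 genes counted at least once. The libraries labelled KO held 13394074 and 14199020 counts, with 18602 and 19020 such genes. At these totals a count of 0 allows at most 0.231 and 0.173 counts per 1000000 counts (CPM) in the libraries labelled WT, and 0.224 and 0.211 CPM in those labelled KO. Intervals and limits of this kind cover counting error alone. Across genes, which are not independent replicates, log2 CPM correlated at 0.98 between the libraries labelled WT, at 0.984 between those labelled KO, and at 0.973 to 0.978 between labels.

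The first question was whether Ppm1k itself, the gene named by the knockout, followed the labels. It did not: both libraries labelled KO held more Ppm1k than both labelled WT. Its counts were 102 and 94 in the libraries labelled WT and 157 and 206 in those labelled KO, or 6.69 ± 1.63 CPM (SD, n = 2) against 13.0 ± 1.74 CPM (SD, n = 2). The deposited FPKM values were 1.25 and 0.859 against 1.86 and 2.3. The fold was 1.96, a log2 fold change of 0.97 with a standard error of 0.23 and 95% limits of 0.41 and 1.53. Over all genes tested its adjusted p was 0.186 by edgeR, and adjusted over the list alone, which holds this 1 gene, it was 0.00451. Ppm1k (ENSMUSG00000037826) lies on chromosome 6 from 57506502 to 57535468 in GRCm38. Counts per gene do not show which exons the reads came from, and a deletion of part of a gene can leave reads elsewhere in it. Without labelled WT replicate 1 the log2 fold change was 1.24 and passed the threshold, with an adjusted p of 0.0278, where the alternatives ranged from 0.0278 to 0.68. On log2(FPKM + 1), where a pseudocount compresses low values, it was 0.59.

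**Figure D1:**
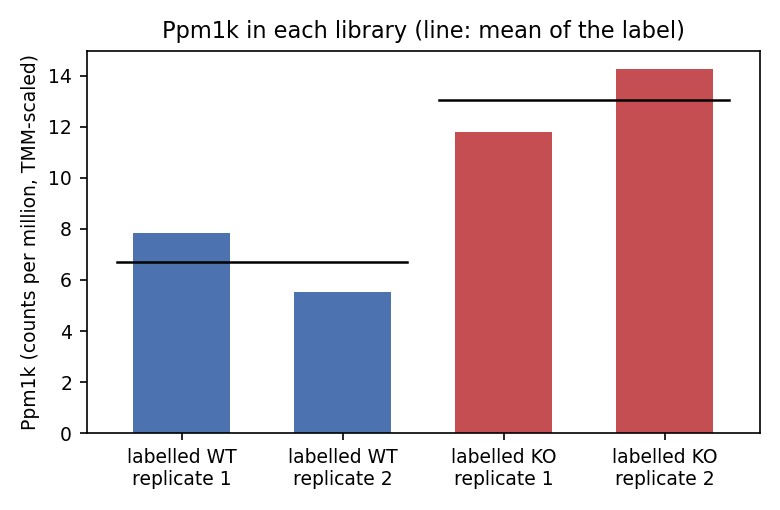
Ppm1k in CPM (vertical axis, TMM-scaled) in each of the 4 libraries, with a line at the mean of each label. The libraries labelled WT stood at 7.84 and 5.53 CPM and those labelled KO at 11.8 and 14.3 CPM, against the order that the genotype labels name.

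The level of Ppm1k goes against the genotype labels, and the labels conflict among themselves. Each library has a genotype field and a title that name 1 genotype, and a description code that begins with the letters of the other. The groups used here follow the genotype field and the title, and every direction is given as the libraries labelled KO against the libraries labelled WT. Every sign would turn if the description codes named the genotype.

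What differs between activated CD8+ T cells of the 2 labels was asked across all genes. Among the genes that rose in the libraries labelled KO were Irf4, a transcription factor whose level follows the strength of T cell receptor signals, Il2ra, the high-affinity chain of the interleukin 2 receptor, Lif, a cytokine of the interleukin 6 family, and Cd200, a membrane ligand of an inhibitory receptor. Irf4 stood at 421 ± 42.7 CPM in the libraries labelled WT and 878 ± 16.4 CPM in those labelled KO (SD, n = 2 each), 2.09-fold higher. Il2ra rose 1.86-fold from 515 ± 10.8 CPM, Lif 2.24-fold from 65.4 ± 7.85 CPM and Cd200 3.88-fold from 23.0 ± 4.44 CPM. Among the genes that fell were Slc16a3, which encodes the lactate exporter MCT4, Asns, which encodes asparagine synthetase, and Ddit4, which encodes REDD1, a stress-induced inhibitor of mTORC1.

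The log2 fold changes of the genes that rose were 1.06 (SE 0.12) for Irf4, 0.90 (SE 0.11) for Il2ra, 1.17 (SE 0.14) for Lif and 1.96 (SE 0.23) for Cd200. Their adjusted p values were 0.0415, 0.0488, 0.0415 and 0.0415. Slc16a3 fell from 115 ± 13.1 to 48.0 ± 4.43 CPM, Asns from 138 ± 18.7 to 58.0 ± 4.05 CPM and Ddit4 from 176 ± 12.0 to 92.2 ± 4.4 CPM (SD, n = 2 each). Their log2 fold changes were −1.26 (SE 0.14), −1.26 (SE 0.14) and −0.93 (SE 0.11), with adjusted p values of 0.0359, 0.0352 and 0.0425. Each of these 7 genes lost its call without labelled KO replicate 2. The adjusted p was then 0.155 for Irf4, 0.164 for Il2ra, 0.181 for Lif, 0.144 for Cd200, 0.14 for Slc16a3, 0.165 for Asns and 0.183 for Ddit4, each the highest among its alternatives, where the lowest were 9.66e-12, 7.39e-10, 4.89e-09, 9.66e-14, 1.21e-09, 5.31e-10 and 6.73e-07. Without labelled KO replicate 1, Slc16a3 (adjusted p = 0.0561), Il2ra (0.0776) and Ddit4 (0.114) also lost theirs. The log2 fold changes themselves stayed within 0.86 and 0.94 for Il2ra and within −1.37 and −1.11 for Slc16a3 over all alternatives. Without labelled KO replicate 2 they were no smaller for Il2ra (0.94), Slc16a3 (−1.35) and Ddit4 (−0.98). They were smaller for Irf4 (1.05), Lif (1.06), Cd200 (1.66) and Asns (−1.18). That fit takes its spread from the labelled WT pair alone, so a lost call does not show that a difference rests on the library left out.

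In all, 28 of 13528 genes tested passed the threshold by edgeR, 14 higher and 14 lower in the libraries labelled KO, and 1749 genes had an unadjusted p under 0.05. DESeq2 called 253 genes, 84 higher and 169 lower, and all 28 were among them. The replicate number as a block gave 123 genes. In 6070 genes, or 44.9%, both libraries of 1 label lay above both of the other, where chance gives 33.3%. The number of calls moved widely as single libraries were left out. Such a fit takes its spread from the pair of the other label alone. The number called then depends on that pair's spread, and does not show how far the differences rest on the library left out. All 28 genes kept their sign with each library left out. The number of calls was 146 with no filter on low counts and 4 on log2(FPKM + 1), of which 2 were among the 28.

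Among the other genes that rose was Prdm16, a zinc finger transcription factor known from brown fat and stem cells, at 2.66 ± 1.35 CPM in the libraries labelled WT and 24.4 ± 4.08 CPM in those labelled KO. Cep290, a protein of the ciliary transition zone, rose from 4.14 ± 0.775 to 18.7 ± 5.07 CPM, and Mob1a, a co-activator of the LATS kinases of the Hippo pathway, from 82.9 ± 15.5 to 279 ± 20.9 CPM (SD, n = 2 each). Their log2 fold changes were 3.23 (SE 0.34), 2.18 (SE 0.26) and 1.75 (SE 0.15). Zfp568, Fam107b, Vkorc1l1 and Eif5, the last a translation initiation factor, rose by 1.63, 1.54, 1.42 and 1.05 on the log2 scale. Plagl2, a zinc finger transcription factor, fell from 232 ± 21.3 to 54.3 ± 17.1 CPM and Hmga1, an architectural chromatin protein, from 179 ± 25.7 to 44.3 ± 11.2 CPM (SD, n = 2 each), with log2 fold changes of −2.09 (SE 0.21) and −2.02 (SE 0.20). Cables1, Ahdc1 and Tmem9b had log2 fold changes of −1.78, −1.68 and −1.35. Without labelled KO replicate 2, Plagl2 kept its call and the adjusted p was 0.0836 for Prdm16, Mob1a and Hmga1, 0.155 for Cep290, 0.154 for Cables1 and Vkorc1l1, 0.12 for Zfp568, 0.161 for Fam107b, 0.14 for Eif5 and 0.183 for Ahdc1 and Tmem9b. Ahdc1 also lost its call without labelled KO replicate 1, with an adjusted p of 0.0921. Fits on log2(FPKM + 1) gave 1.15 for Prdm16 and 0.83 for Cep290, where low values are compressed. Plagl2 lost its call in 2 of its alternatives, with an adjusted p of up to 0.1.

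Pet117 and Gm25951, the called genes with the largest fitted log2 fold changes, lie within other genes. Pet117, an assembly factor of cytochrome c oxidase, had 246 and 348 counts in the libraries labelled WT and 1 and 1 in those labelled KO, a ratio of 275 with a counting interval of 75.7 to 2273. It shares exons on the same strand with Kat14, whose log2 fold change was 0.03 (SE 0.21). Gm25951, annotated as a microRNA inside Rcc2, had 1 and 1 counts against 241 and 240, a ratio of 260 with a counting interval of 71.6 to 2154, and Rcc2 had a log2 fold change of −0.07. Kat14 and Rcc2 were chosen after their values were seen. Such counts are uncertain, because reads of overlapping genes can be divided either way. Eif5 shares exons on the same strand with Snora28, so the fit without exon-sharing genes left it out. Prdm16, Cep290, Hmga1, Cables1, Ms4a4c and Tmem9b overlap genes on the opposite strand, and whether the counting used strand is not given in the sources used here. The 6 called genes outside the naming rule, chosen after their values were seen, were Gm25951, Gm49322 and Gm28036, which rose, and 4930481B07Rik, Gm6758 and Rinl, which fell.

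**Figure D2:**
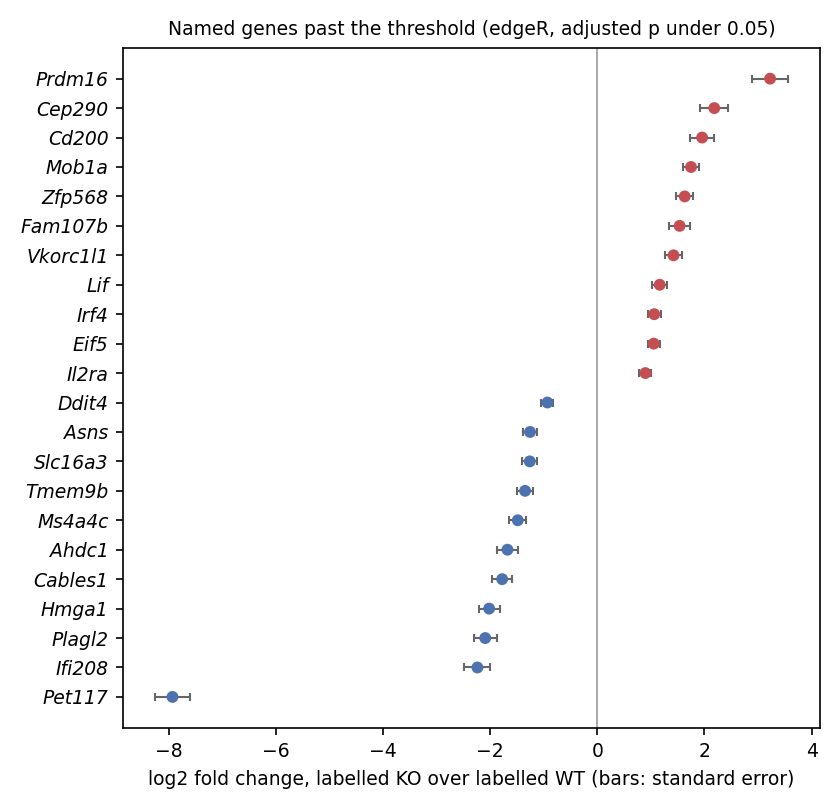
Log2 fold change of the libraries labelled KO over those labelled WT (horizontal axis) of the named genes with an adjusted p under 0.05 by edgeR, with bars for the standard error. Red points rose and blue points fell in the libraries labelled KO. Pet117, with 1 count in each library labelled KO, lies far from the others, and its fitted value depends on the prior count.

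Gene groups were compared through 34 lists fixed before the data were examined, 31 of which had at least 5 members tested. Camera with a preset correlation between genes called 15 of them, 3 higher and 12 lower in the libraries labelled KO. None kept its call with a correlation estimated from these 4 libraries, where adjusted p values started at 0.598, or with fry, where they started at 0.255. A split that sets labelled WT replicate 1 and labelled KO replicate 2 against the other 2 libraries called 18 lists, so some lists move with differences between libraries that neither label names. Of 7 lists of markers of other cell types, 5 summed lower in both libraries labelled KO than in both labelled WT, and no list comparison was adjusted for this. Ighm made up most of the B cell sum and Il2ra most of the CD4 sum. Without them the CD4 sum was lower in both libraries labelled KO and the B cell sum was not.

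Targets of type I interferon, the antiviral cytokine, fell as a group in the libraries labelled KO: 23 of 28 members tested had negative and 5 positive log2 fold changes, with a median of −0.54. Camera gave an adjusted p of 2.12e-08 (adjusted p = 0.598 with an estimated correlation). Cxcl10, which encodes a chemokine that recruits T cells, stood at 4.46 and 9.89 CPM in the libraries labelled WT and at 1.5 and 1.45 CPM in those labelled KO, 4.87-fold lower. The oligoadenylate synthetase Oas3 was 2.21-fold lower, Ifi27l2a 2.1-fold lower and Trim30a 1.43-fold lower, while Oas2, chosen after its values were seen, had a log2 fold change of 1.68. No member passed over all genes by edgeR. At an unadjusted p under 0.05, 16 were lower and 2 higher, DESeq2 called 4 lower, and adjusted over the list alone 14 were lower and 1 higher. In 21 members both libraries labelled KO lay under both labelled WT. Outside the list, the interferon-inducible gene Ifi208 fell from 13.2 ± 1.34 to 2.79 ± 0.622 CPM (log2 fold change −2.24, SE 0.24) and Ms4a4c, of a family of membrane proteins, from 45.1 ± 3.22 to 16.1 ± 1.3 CPM (log2 fold change −1.48, SE 0.16; SD, n = 2 each). Both lost their call without labelled KO replicate 2, each with an adjusted p of 0.154. Summed myeloid markers stood at 241 and 231 CPM in the libraries labelled WT and 169 and 141 CPM in those labelled KO.

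Glycolysis and lactate export, the route of glucose use that activated T cells raise, fell as a group. Of 23 members tested, 20 had negative and 3 positive log2 fold changes, with a median of −0.22 and a camera adjusted p of 3.32e-05 (adjusted p = 0.598 with an estimated correlation). Slc16a3 was the 1 member called by edgeR. Adjusted over the list alone, Aldoc, a fructose-bisphosphate aldolase, also passed, with 12.3 ± 4.14 CPM in the libraries labelled WT and 3.54 ± 0.207 CPM in those labelled KO (SD, n = 2 each), 3.45-fold lower. Members with smaller differences were the glucose transporter Slc2a3, 1.59-fold lower, and the pyruvate dehydrogenase kinase Pdk1, 1.31-fold lower, with adjusted p values of 0.279 and 0.238 over all genes. Slc2a3 stood at 79.4 and 127.5 CPM in the libraries labelled WT and 64.8 and 65.7 CPM in those labelled KO. Its log2 fold change ran from −0.96 to −0.28 as single libraries were left out. The glucose transporter Slc2a1 had a log2 fold change of −0.27 (adjusted p = 0.472), Ldha, a subunit of lactate dehydrogenase, −0.21 (adjusted p = 0.632) and the hexokinase Hk2 0.20 (adjusted p = 0.5). Targets of hypoxia-inducible factor shifted the same way, with 16 of 21 negative, a median of −0.17 and a camera adjusted p of 0.000824 (adjusted p = 0.598 with an estimated correlation). The mitophagy receptor gene Bnip3 was 2.09-fold lower, Ndrg1 2.04-fold lower and Bnip3l 1.65-fold lower. Ddit4 was the 1 member called, and adjusted over the list alone 4 were lower. The glycolysis median was −0.35 without labelled WT replicate 1 and −0.13 without labelled WT replicate 2, and the hypoxia median −0.32 without the latter. In the split of libraries across labels, the glycolysis list moved by a median of 0.21 (adjusted p = 0.00637) and the hypoxia list by −0.02 (adjusted p = 0.659).

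Genes of T cell receptor activation rose as a group: 21 of 27 members tested had positive log2 fold changes, with a median of 0.27 and a camera adjusted p of 1.15e-05 (adjusted p = 0.598 with an estimated correlation). Il2ra was the 1 member called by edgeR. Adjusted over the list alone 6 were higher and 1 lower, among them the orphan nuclear receptor Nr4a3 at 3.51-fold, Nfkbid, a nuclear inhibitor-like regulator of NF-kappaB, at 1.65-fold and the ERK phosphatase Dusp6 at 1.86-fold. Receptors that restrain T cells and genes tied to exhaustion were higher as a list, with a median of 0.22 and an adjusted p of 0.00285 (adjusted p = 0.598 with an estimated correlation), although only 10 of 18 members were positive. Adjusted over the list alone 4 were higher and 1 lower. Besides Cd200, the called member, Btla was 2.29-fold higher, while Ctla4 was 1.59-fold lower and Pdcd1, which encodes PD-1, had a log2 fold change of 0.26 (adjusted p = 0.683) that turned to −0.06 without labelled KO replicate 2. That list lost its call without labelled WT replicate 2 (median 0.13, adjusted p = 0.0506) and without labelled KO replicate 2 (median 0.01, adjusted p = 0.0555), in a range of 9.97e-07 to 0.598 over its alternatives. The activation median was 0.13 without labelled KO replicate 2. In the split of libraries across labels, the activation list had a median of −0.17 (adjusted p = 8.59e-05) and the inhibitory list −0.34 (adjusted p = 0.00825).

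Ribosome biogenesis and MYC targets, a growth programme of dividing T cells, rose as a group, with 31 of 34 members positive, a median of 0.25 and a camera adjusted p of 2.12e-08 (adjusted p = 0.598 with an estimated correlation). The nucleolar proteins Gnl3, Ppan and Wdr43 were 1.39-, 1.36- and 1.29-fold higher, and Myc itself stood at 217 ± 20.9 CPM against 284 ± 1.23 CPM (SD, n = 2 each), 1.31-fold higher. No member passed over all genes by edgeR or DESeq2, or adjusted over the list alone. At an unadjusted p under 0.05, 14 were higher and 0 lower. Both libraries labelled KO lay above both labelled WT in 21 members. The list moved by a median of 0.12 (adjusted p = 0.00198) in the split of libraries across labels.

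Genes of naive and memory T cells fell as a group, with 20 of 26 members negative, a median of −0.34 and a camera adjusted p of 1.24e-05 (adjusted p = 0.614 with an estimated correlation). Ccr7, the receptor that guides T cells into lymph nodes, stood at 661 ± 61.0 CPM in the libraries labelled WT and 393 ± 60.9 CPM in those labelled KO (SD, n = 2 each), 1.68-fold lower. Klf2 was 1.76-fold, S1pr1 1.61-fold, Nsg2 2.21-fold, the transcription factor Tcf7 1.53-fold and Il7r 1.51-fold lower, and Foxo1 had a log2 fold change of −0.03. No member passed over all genes by edgeR, 12 had an unadjusted p under 0.05, of which 11 were lower, DESeq2 called 5 lower and adjusted over the list alone 10 were lower. The list lost its call without labelled WT replicate 1 (median −0.14, adjusted p = 0.0596), in a range of 6.24e-11 to 0.614 over its alternatives. The naive and memory list moved by a median of −0.19 (adjusted p = 0.00825) in the split of libraries across labels. The summed list stood at 4202 and 3504 CPM in the libraries labelled WT and at 3065 and 3064 CPM in those labelled KO. In the same libraries B cell markers, mostly Ighm, summed to 487 and 469 CPM against 377 and 319 CPM. Myeloid markers summed to 241 and 231 CPM against 169 and 141 CPM, and stromal and endothelial markers to 38.3 and 32.7 CPM against 18.6 and 20.1 CPM.

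**Figure D3:**
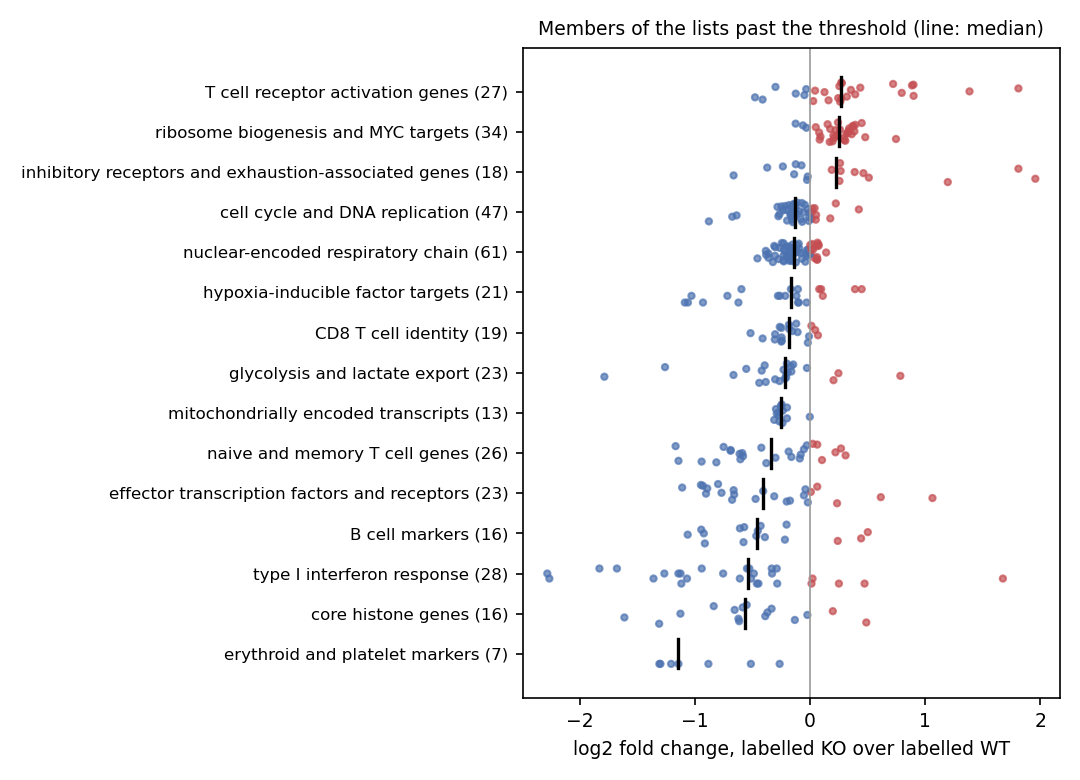
Log2 fold change of the libraries labelled KO over those labelled WT (horizontal axis) of every tested member of the 15 lists called by camera with its preset correlation, with the number of members in brackets and a black line at the median. Red points are positive and blue points negative. Most members of the interferon list lie below 0, with a median of −0.54, and 31 of 34 members of the ribosome biogenesis list lie above it.

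The molecules of effector function moved in both directions. The list of cytotoxic molecules and cytokines had a median of −0.06 and a mean of 0.05, and camera placed it higher with an adjusted p of 0.667, so that median and test differ in sign. It was called higher without labelled KO replicate 1 (median 0.09, adjusted p = 0.00263), had a median of 0.32 (adjusted p = 0.0506) without labelled WT replicate 2 and −0.27 (adjusted p = 0.511) without labelled KO replicate 2, and moved by 0.43 (adjusted p = 9.13e-07) between replicates 1 and replicates 2. Il2, the growth factor of T cells, stood at 1.69 and 1.3 CPM in the libraries labelled WT and at 4.96 and 8.86 CPM in those labelled KO, 4.66-fold higher, with an adjusted p of 0.0883 over all genes and 0.0131 adjusted over the list alone. The inflammatory cytokine Tnf was 1.54-fold higher (0.0284 over the list alone) and the chemokine Ccl5, chosen after its values were seen, had a log2 fold change of −1.39 (0.0131 over the list alone). Ifng had a log2 fold change of 0.68 (SE 0.27, adjusted p = 0.374), Gzmb, the main granule protease, −0.31 (SE 0.23, adjusted p = 0.616) and Prf1, which encodes perforin, −0.13 (SE 0.32, adjusted p = 0.905). No member passed over all genes by edgeR, 4 were higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower. Without labelled WT replicate 2 the value of Gzmb turned to 0.075 and that of Prf1 to 0.42, and without labelled KO replicate 1 Prf1 was at 0.08. Ifng moved between 0.23 and 1.02 as single libraries were left out. Transcription factors and receptors of effector cells were lower as a list, with 18 of 23 members negative, a median of −0.41 and an adjusted p of 0.00478 (adjusted p = 0.598 with an estimated correlation), lost without labelled WT replicate 2 (median −0.20, adjusted p = 0.106), and its median was −0.26 without labelled WT replicate 1. Adjusted over the list alone 1 was higher and 3 lower. Its called member, Irf4, rose, whereas the interferon gamma receptor chain Ifngr1 was 1.86-fold lower (adjusted p = 0.0502), Id2 1.58-fold lower and the chemokine receptor Cxcr3 1.71-fold lower.

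Genes of branched-chain amino acid breakdown, the pathway that PP2Cm serves, showed no shift that passed the test. Of 25 members tested, 18 had negative and 7 positive log2 fold changes, with a median of −0.13 and an adjusted p of 0.386. The median was −0.068 without labelled WT replicate 1 and −0.154 without labelled WT replicate 2. No member passed by edgeR or DESeq2 or adjusted over the list alone, and 1 had an unadjusted p under 0.05. That member was Bckdha, which encodes the E1 alpha subunit on which PP2Cm acts, at 22.9 ± 2.45 CPM in the libraries labelled WT and 15.1 ± 1.14 CPM in those labelled KO (SD, n = 2 each), with a log2 fold change of −0.60 (SE 0.17, adjusted p = 0.238). The kinase of the complex, Bckdk, had a log2 fold change of −0.13 (SE 0.12), and the aminotransferases Bcat1 and Bcat2 had values of 0.10 (SE 0.16) and −0.22 (SE 0.17). The summed list held 1184 and 1219 CPM against 1147 and 1171 CPM. Amino acid transporters had 13 of 17 members positive, a median of 0.16 and an adjusted p of 0.0945, with 0 called by edgeR, by DESeq2 or adjusted over the list alone and 3 at an unadjusted p under 0.05. Their median was 0.096 without labelled WT replicate 2 and 0.195 without labelled KO replicate 2. Slc7a5, the transporter of large neutral amino acids, had a log2 fold change of 0.08 (SE 0.19) that turned to −0.15 without labelled WT replicate 1 and to −0.08 without labelled KO replicate 1, and Bcat1 turned to −0.11 without labelled WT replicate 1.

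Genes of amino acid shortage and stress held 2 called members, Asns and Ddit4, both lower, beside Trib3, a feedback inhibitor of that response, 1.79-fold lower, and Atf3, an early stress transcription factor, 1.68-fold higher. As a list of 27 members they had a median of −0.11 and an adjusted p of 0.0662, with 3 lower and 1 higher adjusted over the list alone. That list was called lower without labelled WT replicate 1 (median −0.20, adjusted p = 0.000316), without labelled KO replicate 1 (median −0.26, adjusted p = 0.00516) and with no low-count filter (adjusted p = 0.021), but its median was 0.06 (adjusted p = 0.943) without labelled WT replicate 2 and 0.01 (adjusted p = 0.404) without labelled KO replicate 2. Genes of mTORC1 amino acid sensing, which also count Ddit4, had a median of −0.01 and an adjusted p of 0.782, with Ddit4 the 1 member passing adjusted over the list alone. The unfolded protein response, 13 of 20 positive, had a median of 0.07 and an adjusted p of 0.145, and 0 of its members were called by edgeR or adjusted over the list alone, 1 by DESeq2 and 3 at an unadjusted p under 0.05. Its median was 0.038 without labelled WT replicate 1 and 0.035 without labelled KO replicate 1. It was 0.124 without labelled WT replicate 2 and 0.093 without labelled KO replicate 2. Asns and Ddit4 lost their calls without labelled KO replicate 2, with adjusted p values of 0.165 and 0.183, and Ddit4 also without labelled KO replicate 1 (0.114).

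Transcripts of the respiratory chain were lower by small amounts. All 13 mitochondrially encoded transcripts had negative log2 fold changes, with a median of −0.26 and an adjusted p of 0.00264 (adjusted p = 0.648 with an estimated correlation), and mt-Cytb stood at 1420 and 1288 CPM in the libraries labelled WT and 1034 and 1170 CPM in those labelled KO. The mitochondrial share of all counts was 1.86% and 1.51% in the libraries labelled WT and 1.34% and 1.51% in those labelled KO. The mitochondrially encoded list moved by a median of −0.22 (adjusted p = 0.00132) in the split of libraries across labels. That list lost its call without labelled WT replicate 1 (median −0.08, adjusted p = 0.321) and without labelled KO replicate 1 (0.0676), and had a median of −0.39 without labelled WT replicate 2. Nuclear-encoded subunits of the chain had 47 of 61 members negative, a median of −0.14 and an adjusted p of 0.00744 (adjusted p = 0.722 with an estimated correlation), with Ndufv2 1.37-fold and Atp5f1 1.31-fold lower. The nuclear list lost its call without labelled WT replicate 2 (median −0.04, adjusted p = 0.766) and without labelled KO replicate 2 (median −0.05, adjusted p = 0.306), had a median of −0.22 without labelled WT replicate 1, and moved by a median of 0.17 (adjusted p = 1.45e-06) in the split of libraries across labels. No member of either list passed by edgeR or DESeq2 or adjusted over the list alone, and 0 mitochondrially encoded and 3 nuclear-encoded members had an unadjusted p under 0.05. Fatty acid oxidation had 15 of 17 members negative and a median of −0.17 (adjusted p = 0.0557, and 0.0239 by DESeq2, 0.0245 with no low-count filter, 0.043 with 5 CPM in 2 libraries, 0.0394 among protein-coding genes, and 0.0175 and 0.0233 on FPKM), with 3 members at an unadjusted p under 0.05 and 0 called by edgeR, by DESeq2 or adjusted over the list alone. The fatty acid oxidation median was −0.10 without labelled WT replicate 2 and −0.095 without labelled KO replicate 2. It was −0.197 without labelled WT replicate 1 and −0.204 without labelled KO replicate 1. Pyruvate dehydrogenase and the TCA cycle had a median of −0.05 (adjusted p = 0.782), the pentose phosphate pathway −0.04 (adjusted p = 0.782), and sterol and fatty acid synthesis a median of 0.06 but a mean of −0.002 (adjusted p = 0.814). Single libraries decided the last of these lists, which was called higher without labelled WT replicate 1 (median 0.44, adjusted p = 3.28e-09) and lower without labelled WT replicate 2 (median −0.24, adjusted p = 1.58e-05), and moved by −0.28 (adjusted p = 1.64e-16) between replicates 1 and replicates 2. Adjusted over the list alone and by edgeR over all genes, 0 members of the pyruvate dehydrogenase, pentose phosphate and sterol lists passed, where 3, 0 and 3 had an unadjusted p under 0.05 and DESeq2 called 1, 0 and 0.

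Cell cycle and DNA replication genes had 38 of 47 members negative, a median of −0.13 and an adjusted p of 0.0137 (adjusted p = 0.648 with an estimated correlation). The mitotic cyclin Ccnb2 was 1.84-fold and E2f2 1.6-fold lower, and both passed adjusted over the list alone, while Ccne2 had a log2 fold change of 0.42. Core histone genes, whose transcripts mostly lack a poly(A) tail, had 14 of 16 members negative, a median of −0.57 and an adjusted p of 0.00621 (adjusted p = 0.648 with an estimated correlation), on summed levels of 55.9 and 73.8 CPM against 47.4 and 42.1 CPM. No member of either list passed over all genes by edgeR. At an unadjusted p under 0.05 the cell cycle list had 3 lower and 1 higher and the histone list 2 lower, DESeq2 called 2 and 0, and 2 and 0 passed adjusted over the list alone. The split of libraries across labels moved the cell cycle list by a median of 0.10 (adjusted p = 0.014) and the histone list by 0.36 (adjusted p = 0.0189). The cell cycle list lost its call without labelled WT replicate 2 (median −0.06, adjusted p = 0.328) and without labelled KO replicate 2 (median −0.08, adjusted p = 0.215). The histone list lost its call without labelled WT replicate 2 (median −0.38, adjusted p = 0.133) by DESeq2 (adjusted p = 0.0588) and after trends with transcript length and GC content were taken out (adjusted p = 0.071), and had a median of −0.31 without labelled KO replicate 2. Apoptosis and p53 targets had a median of 0.01, a mean of −0.09 and an adjusted p of 0.814. Immediate-early and dissociation stress genes had a median of 0.02, a mean of −0.02 and an adjusted p of 0.962, with camera placing them higher. Neither of these lists had a member passing by edgeR or adjusted over the list alone, where 1 and 4 had an unadjusted p under 0.05 and DESeq2 called 0 and 1.

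Genes of CD8 T cell identity were lower by small amounts, with 16 of 19 members negative, a median of −0.18 and an adjusted p of 0.00392 (adjusted p = 0.598 with an estimated correlation), lost without labelled WT replicate 1 (median −0.12, adjusted p = 0.106). Cd3d was 1.43-fold and Cd3g 1.33-fold lower, and Cd8a stood at 533 ± 13.5 CPM against 529 ± 25.2 CPM (SD, n = 2 each), a log2 fold change of −0.01 that crossed 0 under library size alone. No member passed by edgeR or DESeq2 or adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05. B cell markers summed to 487 and 469 CPM against 377 and 319 CPM, with a list median of −0.46 and an adjusted p of 0.0367 (adjusted p = 0.648 with an estimated correlation), lost without labelled WT replicate 2 (median −0.08, adjusted p = 0.577) and without labelled KO replicate 2 (median −0.15, adjusted p = 0.863). It was also lost among protein-coding genes (adjusted p = 0.131), without exon-sharing genes (0.0508) and after trends with transcript length and GC content were taken out (0.103). The median was −0.73 without labelled WT replicate 1 and −0.94 without labelled KO replicate 1. The B cell list moved further in the split of libraries across labels, by a median of 1.03 (adjusted p = 2.335e-07). Ighm made up most of the summed B cell markers, at 406 and 345 CPM against 286 and 257 CPM. Without Ighm the sum was not lower in both libraries labelled KO than in both labelled WT. H2-Eb1, an MHC class II gene, stood at 3.3 and 12.1 CPM against 5.04 and 3.18 CPM. Erythroid and platelet markers, at 11.3 and 20.5 CPM against 7.67 and 7.41 CPM, had all 7 members negative and an adjusted p of 0.00421 (adjusted p = 0.598 with an estimated correlation), lost without labelled WT replicate 2 (median −0.50, adjusted p = 0.16). Neither list held a member called by edgeR or DESeq2 or adjusted over the list alone, and each had 2 at an unadjusted p under 0.05.

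Myeloid markers had a list median of −0.46 (adjusted p = 0.0619) and dendritic cell markers −0.44 (adjusted p = 0.353), the latter on sums of 200 and 228 CPM against 212 and 174 CPM. The myeloid list was called lower without labelled WT replicate 1 (median −0.59, adjusted p = 0.000507), without labelled KO replicate 1 (median −0.67, adjusted p = 0.00516) and with no low-count filter (adjusted p = 0.0255), but its median was 0.07 (adjusted p = 0.577) without labelled WT replicate 2 and −0.24 (adjusted p = 0.215) without labelled KO replicate 2. The dendritic median was −0.04 without labelled WT replicate 2 and −0.20 without labelled KO replicate 2. The split of libraries across labels moved the myeloid list by a median of 0.60 (adjusted p = 0.00193) and the dendritic list by 0.37 (adjusted p = 0.0227). NK and gamma-delta T cell markers summed to 56.0 and 61.9 CPM against 47.9 and 43.7 CPM and had a median of 0.25 (adjusted p = 0.854). That median was −0.079 without labelled WT replicate 1, 0.609 without labelled WT replicate 2 and 0.445 without labelled KO replicate 2. Stromal and endothelial markers, 2 of them tested, summed to 38.3 and 32.7 CPM against 18.6 and 20.1 CPM. Adjusted over the list alone, 1 member was lower in each of the myeloid, NK and stromal lists and 0 in the dendritic list. The dendritic list also had 0 members called over all genes by edgeR, 0 by DESeq2 and 0 at an unadjusted p under 0.05. CD4 and regulatory T cell markers summed higher in the libraries labelled KO, at 618 and 612 CPM against 1060 and 1004 CPM, with a median of 0.59 and an adjusted p of 0.107. That list was called higher without labelled KO replicate 2 (median 0.94, adjusted p = 0.00502) and with no low-count filter (median 0.81, adjusted p = 0.0255). Il2ra, which activated CD8 T cells also express, made up most of the summed markers, at 523 and 508 CPM against 983 and 937 CPM. Without Il2ra the sum was lower in both libraries labelled KO than in both labelled WT. Cd4, chosen after its values were seen, was 1.94-fold higher (adjusted p = 0.369). Genes of the Y chromosome were read in all 4 libraries, and the 4 sex-chromosome genes tested had a median of 0.05, with 0 called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05.

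**Figure D4:**
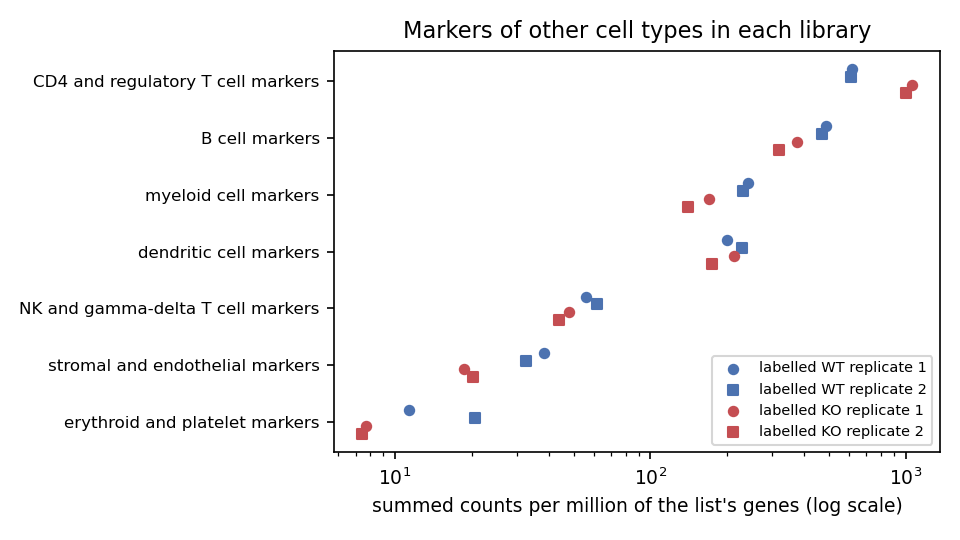
Summed CPM (horizontal axis, log scale) of marker genes of other cell types in each library, with blue for the libraries labelled WT and red for those labelled KO. B cell markers lay between 319 and 487 CPM and were lower in both libraries labelled KO. CD4 and regulatory T cell markers stood at 618 and 612 CPM against 1060 and 1004 CPM in the libraries labelled KO. Ighm made up most of the B cell sum and Il2ra most of the CD4 sum. Without them the CD4 sum was lower in both libraries labelled KO and the B cell sum was not.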

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

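The FPKM fits, the crossed block and the fit without exon-sharing genes were chosen after the data had been seen, and the planned fits on TPM were not run because the table holds FPKM. Every sign here and in the report turns if the description codes, and not the genotype labels, name the genotype. Each of the 28 called genes kept its sign under every alternative in which it was tested. The number called was 28 with DESeq2's size factors in edgeR, 21 with library size alone and 26 with a threshold of 2-fold. It moved further under the alternatives that follow, and the cause was not tested. By DESeq2 84 genes were higher and 169 lower, with no low-count filter 45 and 101, with 5 CPM in 2 libraries 27 were lower, among protein-coding genes 23 were lower, and without exon-sharing genes 29 were lower. FPKM with either pseudocount called 2 higher and 2 lower. The replicate block gave 46 higher and 77 lower, although deviations of same-numbered replicates correlated at −0.168 across genes and gave no sign of pairing. The crossed block called 8 higher and 4 lower. With single libraries left out, 3 to 127 genes were higher and 5 to 177 lower, fewest without labelled KO replicate 2, the log2 fold change of Ppm1k was 0.73 to 1.24, and 2 to 4 lists were higher and 7 to 13 lower. With an estimated correlation and with fry, 0 lists were higher and 0 lower. Signs of 8 named genes that had not passed the test turned, and the cause was not tested. Cd8a stood at 0.007 under library size alone and at 0.008 under both FPKM fits. As single libraries were left out, log2 fold changes ran from −0.059 to 0.043 for Cd8a, from −0.088 to 0.039 for Foxo1, from −0.11 to 0.355 for Bcat1, from −0.146 to 0.367 for Slc7a5, from −1.55 to 0.311 for H2-Eb1, from −0.612 to 0.075 for Gzmb, from −0.517 to 0.42 for Prf1 and from −0.056 to 0.513 for Pdcd1. The turn came without labelled WT replicate 1 for Cd8a (0.022), Foxo1, Bcat1 and Slc7a5, without labelled WT replicate 2 for H2-Eb1, Gzmb and Prf1, without labelled KO replicate 1 for Prf1 (0.08) and Slc7a5 (−0.081), and without labelled KO replicate 2 for Cd8a, Foxo1 (0.012) and Pdcd1. At 12967251 to 17316284 counts a library, a count of 0 allows at most 0.173 to 0.231 CPM, and how far depth limits the calls was not tested.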

Other observations

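The term tests, the weighing of patterns and the counts of genes near one another in this part were chosen after the results had been seen, except those of single libraries on Ppm1k and of transcript length and GC content. Among 3483 Gene Ontology terms, camera with its preset correlation called 10 higher and 42 lower in the libraries labelled KO, and 0 with an estimated correlation. The term with the smallest p was T cell migration, with 29 of 33 genes negative and a median of −0.37 (adjusted p = 9.48e-05, and adjusted p = 0.982 with an estimated correlation). Beyond Ccr7 and S1pr1, it held the integrin gene Itgb7 at 156 and 178 CPM in the libraries labelled WT and 115 and 91.4 CPM in those labelled KO, the chemokine receptor Cxcr3 at 53.2 and 68.6 against 36.0 and 35.4 CPM, and Ripor2 at 86.0 and 84.1 against 57.4 and 61.7 CPM. The chemokine Ccl5 stood at 14.7 and 22.4 against 6.09 and 8.1 CPM. In the crossed split this term had an adjusted p of 0.709, although 32 terms were called there.

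Genes of the preribosome, with 58 of 70 positive, had a median of 0.20 (adjusted p = 0.000133, and 0.982 with an estimated correlation). Mdn1, an ATPase of ribosome assembly, had a log2 fold change of 0.52, and Wdr3 and Krr1, of the small-subunit processome, 0.37 each. Genes of the cellular response to interferon-beta, with 24 of 30 negative, had a median of −0.30 (adjusted p = 0.000951, and 0.982 with an estimated correlation). The GTPases Gbp3 and Gbp2 stood at 36.1 and 32.3 against 16.8 and 18.8 CPM and at 588 and 405 against 338 and 303 CPM. The 45 genes of respiratory complex I had 40 negative members and a median of −0.20 (adjusted p = 0.0371, and 0.982 with an estimated correlation). The genes named in this and the preceding paragraph were chosen after their values were seen, except Ccr7, S1pr1 and Cxcr3.

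Ppm1k stood higher in both libraries labelled KO. A single library was argued against as its cause, since the lowest log2 fold change with 1 of the 4 left out was 0.734. Whether the description codes, and not the genotype fields, name the genotype stays open. The conflict was seen in the labels before the counts, and Ppm1k was planned as the check. Its level goes with the description codes, but it cannot decide, since a deletion of part of a gene can leave reads elsewhere in it. Scaling by 1 factor per library was argued against as the cause. The log2 fold change was 0.979 with DESeq2's size factors and 0.989 with library size alone, and TMM factors ran from 0.982 to 1.019. A bias that differs between genes was not tested, since each scaling tried applies 1 factor to all genes of a library. A changed allele can also leave or raise reads of its gene, which counts per gene do not show, and no sample was moved.

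In 17 genes, both libraries of 1 label had at most 2 counts and both of the other at least 10, with 5 low in the libraries labelled WT and 12 low in those labelled KO, against 2 and 7 genes in the other splits. Of these 17, 35.3% share exons on the same strand with another gene, against 9.1% of all tested genes (Fisher's exact test, odds ratio 5.47, p = 0.00287). Reads divided between overlapping genes may account for some of them. For Pet117, at 19.7 CPM in the libraries labelled WT, its partner Kat14 showed no matching gain, at 55.2 CPM labelled WT and 56.5 CPM labelled KO. The standard error of Kat14, 0.21 on the log2 scale, leaves this undecided. Rcc2, at 800 and 764 CPM, is too high to tell for Gm25951. Division of reads cannot account for the 8 that share no exon on either strand. Among those 8, Arhgef16, chosen after its values were seen, had 28 and 60 counts in the libraries labelled WT and 0 in those labelled KO, at least 27.1-fold lower against 3 counts over the label. Stretches of another genetic background around such genes are a candidate explanation: of 133 genes with an unadjusted p under 0.001, 41 lay within 1 Mb of another, where random draws of genes of like level gave a median of 25 and a share of 0.0055 as large, and the other splits gave 25 and 14. A stretch carried with Ppm1k cannot be told apart from chance, since 7.9% of the 89 genes within 10 Mb had an unadjusted p under 0.01 against 4.17% elsewhere (Fisher's exact test p = 0.101) and the window holds few genes.

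The type I interferon and glycolysis lists were lower in the libraries labelled KO. Transcript length and GC content were argued against as the whole cause, since the larger camera p of the pair was 8.65e-05 after their trends were taken out. Cells of other types in the libraries labelled WT stay open, since 5 of 7 marker lists of other cell types summed lower in both libraries labelled KO, and their share cannot be told apart from the label in 4 libraries. The B cell and CD4 sums were mostly Ighm and Il2ra. Without these genes the CD4 sum was lower in both libraries labelled KO and the B cell sum was not. Differences between libraries that follow neither label could account for the glycolysis list, whose median reached 0.209 in another split against −0.22 here, and for the interferon list the same test gave 0.165 against −0.54, which keeps a part of that size open. The genotype stays a possible explanation for both lists, untested and of a direction that depends on which labels hold.

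For the genes called between the labels, 28 were called in the real split and at most 1 in the others. There are 3 splits of the 4 libraries into pairs, too few for a share under 0.05, and 1 of them, the real one, gave as many.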
